A study of Homo sapiens with 3 samples.

How the data were processed

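RNA was measured in THP-1, an established human monocytic leukaemia cell line, on 3 Affymetrix Human Gene 1.0 ST arrays, 1 per condition. Per the labels' protocols, the cells received LPS at 0.2 µg/ml or plain medium for 3 hours. They then received nigericin at 10 µM or its ethanol vehicle for 2 hours. Whether LPS stayed in the medium during these 2 hours is not given in the sources used here, so the LPS array may stand for continued LPS or for LPS followed by its removal. Total RNA was labelled with a whole-transcript sense-strand kit. The 3 groups were control, LPS, and LPS followed by nigericin. Groups were taken from the labels alone.

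The deposited table held 33297 probe sets with no missing value. Per the submitters' processing notes, the values were made with RMA in Affymetrix Expression Console, and versions are not given in the sources used here. RMA in general corrects background, quantile-normalizes the arrays and summarizes the probes of a probe set by median polish. The deposited values were used as log2 expression, although the base of the logarithm is not stated. The base was inferred from the values, because the maximum was 14.1 on every array, and the same number as a natural or base 10 logarithm would exceed the range of a 16-bit scanner. Array medians were 6.85 for control, 6.86 for LPS and 6.91 for LPS plus nigericin. Pearson's r across probe sets, which are not independent replicates, was 0.996 for LPS against control, 0.99 for LPS plus nigericin against LPS and 0.987 for LPS plus nigericin against control. Precision is limited by the number of arrays, 1 per group. No background signal or detection call was used here, so a low value is not shown to be above background.

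Median polish over 3 arrays affects small differences. On 58.4% of all probe sets at least 2 arrays held exactly the same value, and on 33.5% all 3 did. In a simulation with 25 probes per probe set and a probe SD of 0.3, a true log2 difference of 0.2 on 1 array was estimated at 0.071 on average. A true difference of 0.5 was estimated at 0.37, and a true difference of 1 at 0.871. Printed differences can therefore understate true ones, most of all small ones, and a difference of exactly 0 does not show that a level was the same.

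Probe sets were named through the platform's annotation table, which listed 21214 of them. Of these, 19460 had 1 gene symbol and 1754 had several, and the latter named no gene. The other 12083 probe sets were unnamed here. Entrez identifiers of 19429 of the 1-symbol probe sets matched the RefSeq gene table of GRCh38.p14 and 31 did not, and 0 symbols changed in this update. Where a gene had several probe sets (769 genes), the probe set with the highest mean over the 3 arrays stood for it, which left 18417 genes. Where probe sets of a gene gave different values, the range stands beside the genes for which the text reports it.

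With 1 array per group, no test, standard error or p-value was computed, and "higher" and "lower" describe the arrays. The log2 difference between 2 arrays was taken for LPS against control, LPS plus nigericin against LPS, and LPS plus nigericin against control. A gene counted as measured in a comparison when its higher array of the pair was at or above 6.88, the median of all values, and as different when the difference was at least 2-fold. Genes were named by a fixed rule. It took the 12 largest differences in each direction in the first 2 comparisons, and the 5 largest in the third. It added up to 4 members of each gene list with the largest absolute differences, and always NLRP3, PYCARD, CASP1, IL1B, IL18 and TNF. Members of the small non-coding RNA list were not to be named one by one. The rules, the lists and the alternatives were fixed before the data were examined.

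The 29 gene lists covered inflammasome components, the IL-1 family and its receptors, cytokines and growth factors, chemokines, NF-kB feedback and survival targets, type I interferon-induced genes, immediate early genes, MAP kinase phosphatases with Sprouty proteins, ATF4 targets, the ER unfolded protein response, heat shock, NRF2 targets, metallothioneins with zinc transporters, cholesterol synthesis, hypoxia with glycolysis, lysosome with autophagy, p53 targets, apoptosis with necroptosis, cell cycle, ion transport, monocyte identity, other blood cell types, epithelial with stromal and endothelial types, housekeeping genes, ribosomal proteins, mitochondrially encoded genes, small non-coding RNAs, replication-dependent histones and ZNF genes. The mitochondrially encoded list matched 0 of the genes named here, so it had 0 measured members whatever their level. For each list the members at least 2-fold higher, at least 2-fold lower and between were counted. The list's median was placed among the medians of 10000 random gene lists of the same size, matched on mean level in 20 bins. This percentile describes these arrays and is not a test of the conditions. Because so many differences were exactly 0, random medians crowded at 0 and a small median could reach an extreme percentile. The mean and its percentile were therefore added, a choice made after seeing the data.

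Alternatives were centring each pair on its median difference, a loess of the difference on level with span 0.3, no level filter, a filter at the 75th percentile of all values, the mean of all probe sets of a gene, and thresholds of 1.5-fold and 3-fold. The procedure was tested on simulated arrays with errors drawn from LPS against control differences with random signs, real differences included. Of genes raised and lowered by 1.5 on the log2 scale, 100.0% and 100.0% were recovered for LPS against control, 100.0% and 96.0% for LPS plus nigericin against LPS, and 100.0% and 98.0% for LPS plus nigericin against control. The simulations held 10842, 10841 and 10827 genes in the same order, the changed ones included. Unchanged genes past 2-fold numbered 73, 85 and 80. These counts treat real LPS differences as error, and no replicate gives the error alone. The changes were added to summarized values, so shrinkage by median polish did not enter, and 1.5 lies well past the threshold. Recovery on real arrays is therefore not shown. Errors came from LPS against control for the nigericin pairs too. Differences across probe sets had an SD of 0.348 and 0.392 in those pairs, against 0.214 for LPS against control. Of 40 simulated lists without a shift, 0, 1 and 2 lay outside the central 95% of random lists. Those lists were drawn at random from the same values as their references, so this share was set in advance. It does not cover lists of genes that change together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.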

Results

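Expression was profiled in THP-1 cells under the conditions used to prime and then activate the NLRP3 inflammasome, the cytosolic complex that activates caspase-1 and the release of IL-1β. LPS, a bacterial ligand of TLR4, gave the priming signal, and nigericin, a potassium ionophore, gave the activating signal. The study set out to find genes that respond to this activation. There was 1 array for each of the 3 conditions and there were no replicates, so each difference is between 2 cultures and its error is unknown. Nigericin without LPS was not analysed here, so its effect on unprimed cells cannot be separated from its effect after LPS.

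CXCL10, a chemokine of the interferon response, was at a log2 level of 11.56 on the LPS array and 4.91 on the control array, a 100.4-fold difference between the listed values. TNFAIP6, which encodes a hyaluronan-binding secreted protein, was 59.1-fold higher, EBI3, a subunit of IL-27 and IL-35, was 22.3-fold higher, and TNIP3, a partner of the NF-kB inhibitor A20, was 19.2-fold higher. The Notch coactivator MAML2 was 8.40-fold higher and CD80, a costimulatory ligand for T cells, was 7.70-fold higher. The adhesion molecule ICAM1 was 6.88-fold higher, the NF-kB subunit NFKB2 6.17-fold, the mitochondrial superoxide dismutase SOD2 5.92-fold and TNFAIP3, which encodes A20, 5.41-fold. RIPOR2 was higher by a log2 difference of 2.43, and RASGRP1, a Ras activator, was 4.86-fold higher. The control values of CXCL10, TNFAIP6, EBI3, TNIP3, MAML2, CD80, RIPOR2 and RASGRP1 lay below the level filter of 6.88 and were not shown to be above background, so these folds compare listed values and their exact sizes are uncertain.

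Of 10919 measured genes, 79 were at least 2-fold higher after LPS and 1 was at least 2-fold lower. That gene was SYNPO2, an actin-associated protein, which was 2.05-fold lower. Just short of the threshold were the nucleotide receptor P2RY2, 1.99-fold lower, carbonic anhydrase CA2, 1.98-fold lower, the inhibitory receptor CD300A, 1.93-fold lower, and the selectin ligand SELPLG at a log2 difference of -0.94. NFE2, SLC38A12, DGKG, CORO2A, NHERF1, EPAS1 and MTARC1 followed, at log2 differences from -0.91 to -0.74. The numbers of genes depend on the threshold, since 185 genes were higher and 33 lower at 1.5-fold. The values were exactly equal on both arrays for 37.5% of the measured genes.

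NF-kB feedback and survival targets formed the list with the most members past the threshold after LPS. Of 28 measured members 14 were at least 2-fold higher, 0 lower and 14 between, with a median log2 difference of 0.97 (percentile 100.0 of the random lists). Of 8 measured chemokines 2 were higher, CXCL10 and the monocyte attractant CCL2 (4.24-fold), and 0 lower, with a median of 0.67 (percentile 100.0). With the level filter at the 75th percentile the median was 1.59 for the NF-kB list and 2.08 for chemokines, the latter being the value of CCL2 itself. CCL3 and CXCL8 lay below the threshold at 0.93 and 0.84. Among 12 cytokines and growth factors EBI3 and TNF (2.24-fold) were higher and 0 lower, with a median of 0.11 (percentile 99.99). IL23A, at 0.49, did not reach the threshold. The median of 23 type I interferon-induced genes was 0.35 (percentile 100.0). GBP2, a guanylate-binding GTPase, was 2.98-fold higher and the RNA sensor IFIH1 2.47-fold, while the other 21 members lay between the thresholds, IRF9 at 0.95 and OAS2 at 0.79 among them. The other probe set of GBP2 gave 1.72 against 1.58, and the control values of GBP2 and IFIH1 (6.23 and 6.29) lay below the level filter, so the exact sizes of these folds are uncertain. All 10 metallothionein and zinc genes lay between the thresholds, yet 9 were above 0 and their median was 0.34 (percentile 100.0), with MT2A at 0.89 (other probe sets down to 0.75) and MT1M at 0.84. The 16 NRF2 targets had a median of 0.15 (percentile 100.0) with 0 past the threshold, led by the malic enzyme ME1 at 0.89.

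Inflammasome components showed no shared direction after LPS. The sensor NLRP3 was at -0.17, the adaptor PYCARD at -0.38 and CASP1 at 0.28. The ATP-gated channel P2RX7 was at 0.85, NINJ1, a mediator of membrane rupture, at 0.72, and NAIP, a sensor of bacterial proteins, at -0.74, with other probe sets of it up to -0.58. All 14 measured members lay between the thresholds, with a median of -0.0125 (percentile 13.2), which was 0.0159 with the filter at the 75th percentile, and a mean of 0.029. IL1B was 2.91-fold higher, from a control value of 6.09 below the level filter, and IL18 was at -0.005. Of the 4 measured members of the IL-1 family list, IL1B was the member past the threshold. The list's median of -0.0026 (percentile 40.2) and its mean of 0.36 (percentile 97.7) differed in sign.

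Immediate early genes, which growth factors and stress induce within minutes, held 2 of 29 members at least 2-fold higher after LPS, SGK1 (2.48-fold) and PHLDA1 (2.04-fold, from a control value of 6.86 just below the level filter), and 0 lower. Their median was 0.037 (percentile 100.0), and the mean of 0.11 lay at percentile 98.1. Of 22 monocyte identity genes the alarmin S100A12 was 2.13-fold higher and 0 were lower, with a median of -0.0246 (percentile 4.99) and a mean of opposite sign, 0.079. No member passed the threshold among the 18 cholesterol genes (median 0.054, percentile 99.96), the 20 ER unfolded protein response genes (0.024, percentile 99.3), the 17 heat shock genes (0.0077, percentile 96.2), the 12 MAP kinase phosphatases and Sprouty genes (0.0078, percentile 97.55, but -0.0432 with the filter at the 75th percentile), the 26 ATF4 targets (0.005, percentile 99.6) or the 50 histone genes (0.0016, percentile 99.9). The means of these lists, which exact ties affect less, lay at percentiles 98.3 for cholesterol, 93.6 for the unfolded protein response, 86.3 for heat shock, 89.5 for phosphatases and Sprouty, 77.6 for ATF4 targets and 86.1 for histones. The same held for the 27 hypoxia and glycolysis genes, with a median of -0.0091 (percentile 9.2) and the mean at percentile 44.7. Medians were exactly 0, with 0 members past the threshold, for 25 lysosome and autophagy genes, 14 p53 targets, 19 apoptosis and necroptosis genes, 29 cell cycle genes, 18 ion transport genes, 22 housekeeping genes, 60 ribosomal protein genes, 166 small non-coding RNAs and 366 ZNF genes. The small non-coding RNAs nevertheless had 81 members above 0 and 52 below, and their mean of 0.070 lay at percentile 99.6. Markers of other cells were few above the level filter. The 5 measured markers of other blood cells and the 3 of epithelial, stromal and endothelial cells had 0 members past the threshold and medians of 0.

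**Figure D1:**
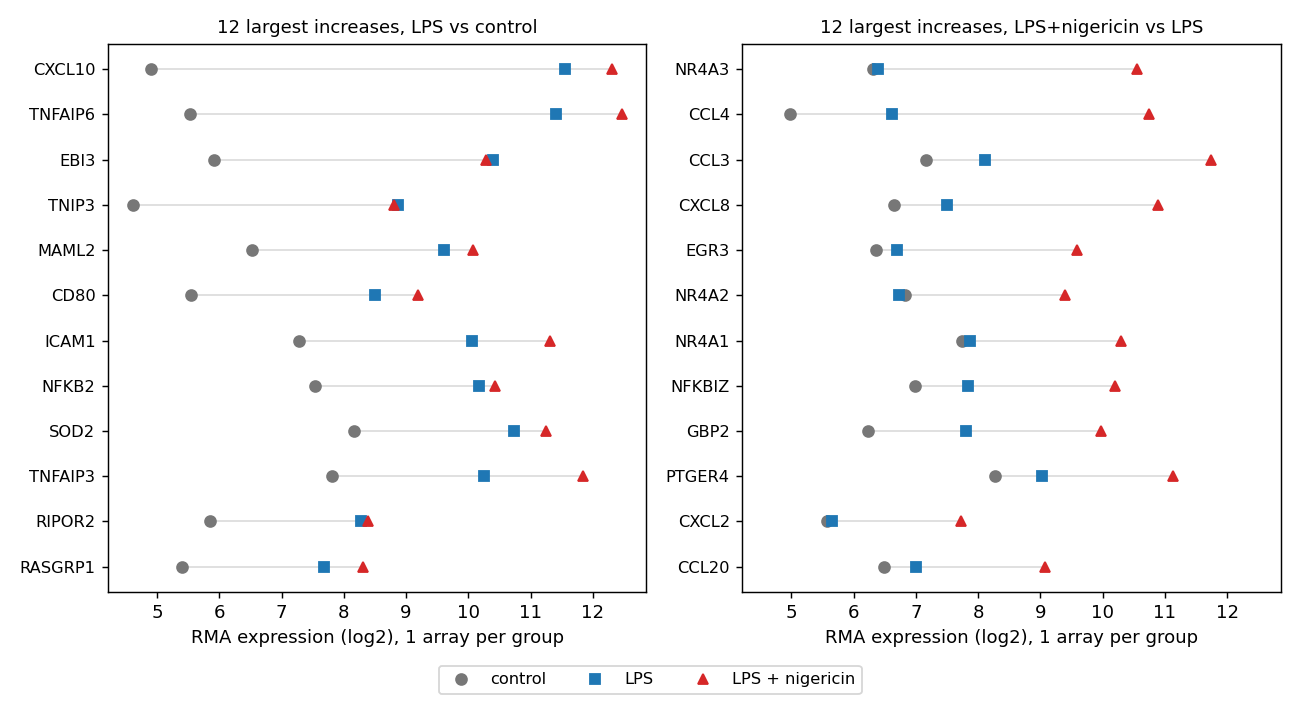
Log2 RMA expression (horizontal axes) of the 12 genes with the largest increases from control to LPS (left) and from LPS to LPS plus nigericin (right); each point is 1 array, with grey circles for control, blue squares for LPS and red triangles for LPS plus nigericin. CXCL10 lay at 4.91 on the control array and 11.56 on the LPS array, whereas NR4A3 lay at 6.39 on the LPS array and 10.55 after nigericin.

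After nigericin was added to LPS-treated cells, the orphan nuclear receptors of the NR4A family, which are immediate early genes, and 5 of 10 measured chemokines were at least 2-fold higher. NR4A3 was 18.0-fold higher than on the LPS array, NR4A2 6.35-fold and NR4A1 5.33-fold. Among chemokines CCL4 was 17.5-fold higher, CCL3 12.5-fold, CXCL8 10.5-fold, CXCL2 4.21-fold and CCL20 4.18-fold. The transcription factor EGR3 was 7.37-fold higher, the atypical IkB protein NFKBIZ 5.09-fold, GBP2 4.50-fold and the prostaglandin E2 receptor PTGER4 4.31-fold. The other probe set of GBP2 gave a smaller log2 difference, 1.17 against 2.17. On the LPS array NR4A3, NR4A2, CCL4, EGR3 and CXCL2 lay below the level filter, so the exact sizes of their folds are uncertain, and CCL3 and CCL4 have near-identical gene copies that their probes may not separate.

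At the other end MTND2P28 was 3.92-fold lower with nigericin. This nuclear pseudogene is nearly identical to the mitochondrial ND2 gene, so the source of its signal is uncertain. The proton-sensing receptor GPR65 was 3.59-fold lower, KRCC1 3.49-fold, the ubiquitin ligase TRIM59 2.95-fold and the transporter SLC16A14 2.79-fold, and FAM200A had a log2 difference of -1.48. S100A12 was 2.71-fold lower, the transcription factor NFE2 2.65-fold, SPA17 2.59-fold, the cytochrome P450 CYP1B1 2.52-fold and the iron exporter SLC40A1 2.47-fold. The isocitrate dehydrogenase IDH1 had a log2 difference of -1.32. With nigericin GPR65, FAM200A, NFE2 and SLC40A1 lay below the level filter. In all, 63 of 10979 genes were at least 2-fold higher and 61 at least 2-fold lower. The balance between directions depended on the threshold, since 258 genes were higher and 498 lower at 1.5-fold, and 19 higher and 4 lower at 3-fold. The values were exactly equal for 23.5% of the measured genes.

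Of the inflammasome genes, NLRP3 was 1.62-fold lower with nigericin than on the LPS array, CASP1 was 1.57-fold lower and PYCARD was at -0.58 on the log2 scale, while P2RX7 was at 0.58. None of the 13 measured components passed the threshold, and their median was -0.23 (percentile 2.46, with the mean of -0.19 at percentile 6.82). IL1B was 2.54-fold higher and IL18 was 1.97-fold lower. The 4 measured IL-1 family genes had 1 member higher, IL1B, 0 lower and a median of 0.078 (percentile 91.0), or 0.71 with the level filter at the 75th percentile. That filter left IL1B (log2 difference 1.35) and IL1RN (0.07) alone, and IL1B passed it through the nigericin array.

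With nigericin, of 10 measured chemokines 5 were at least 2-fold higher, 0 lower and 5 between, with a median of 1.41 (percentile 100.0). Without the level filter, which adds chemokines near the bottom of the range, the median was 0.085, and it was 2.06 with the filter at the 75th percentile. CCL4 and CXCL2 counted here through the nigericin array alone and were not among the 8 chemokines measured for LPS against control. CCL4 was nevertheless at 4.98 on the control array and 6.61 on the LPS array. The chemokine medians of the 2 steps therefore cover different genes. Of 32 immediate early genes 9 were higher, 2 lower and 21 between, with a median of 0.35 (percentile 100.0). NR4A3, EGR3 and NR4A2, among the 9, counted through the nigericin array alone. They were not among the 29 measured for LPS against control, so the immediate early medians of the 2 steps also cover different genes. Of 28 NF-kB targets 9 were higher and 0 lower, with a median of 0.41 (percentile 100.0). Prostaglandin synthase PTGS2 was 3.90-fold higher, TNFAIP3 3.01-fold and the IkB protein NFKBID reached 1.59 on the log2 scale. Of 13 cytokines and growth factors 3 were higher, IL23A (2.92-fold), TNF (2.81-fold) and TNFSF9 (2.41-fold), and 1 was lower, the death ligand TNFSF10 (2.03-fold), with a median of 0.48 (percentile 100.0). Among 23 type I interferon-induced genes GBP2 was higher, and IFIT5 (2.19-fold, to a value of 5.92 below the level filter) and SAMD9 (2.09-fold) were lower. The list's median was -0.11 (percentile 3.11, with the mean of -0.21 at percentile 1.04). With LPS plus nigericin against control, 2 of 22 measured interferon-induced genes were higher and 0 lower, with a median of 0.094 (percentile 99.96). This list was also high on the LPS array, which both steps share with opposite signs.

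Signalling feedback and stress lists were mixed. Of 12 MAP kinase phosphatase and Sprouty genes DUSP1 was 2.77-fold higher, DUSP6 was 2.22-fold lower and 10 lay between, with a median of 0.029 (percentile 97.0) and the mean at percentile 98.3. The median turned to -0.38 with the filter at the 75th percentile. Of 26 ATF4 targets 2 were higher, the eIF2α phosphatase subunit PPP1R15A (3.21-fold) and GADD45B (2.41-fold), and 0 lower, while the median was -0.17 (percentile 2.13) and the mean -0.046 (percentile 62.6). PLK3 was 2.17-fold higher among 14 p53 targets, whose median was 0 (percentile 70.7) with 0 lower. The potassium channel KCNJ2 was 2.15-fold higher among 18 ion transport genes, whose median was 0.042 (percentile 99.5) with 0 lower. No member passed the threshold among 20 ER unfolded protein response genes (0.10, percentile 99.95), 18 cholesterol genes (0.082, percentile 99.9), 27 hypoxia and glycolysis genes (0, percentile 81.5, with a mean of 0.079 at percentile 99.0), 25 lysosome and autophagy genes (0, percentile 82.2) or 19 apoptosis and necroptosis genes (-0.056, percentile 14.4).

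With nigericin, of 16 NRF2 targets 2 were at least 2-fold lower, the antioxidant enzyme gene SRXN1 (2.27-fold) and the glutathione synthesis subunit GCLM (2.12-fold, to 6.80, below the level filter), and 0 higher, with a median of -0.27 (percentile 0.31). NQO1 just missed the threshold at -0.98, and AKR1C1 stood at 0.51 on one probe set and -0.24 on another. Against control 0 of 15 measured NRF2 targets passed the threshold with LPS plus nigericin, with a median of -0.21 (percentile 3.92). Their mean was -0.15 (percentile 19.5), SRXN1 was at -0.78 and GCLM at -0.65. The LPS array enters both steps with opposite signs. A high value on it alone would raise this list after LPS and lower it with nigericin. Of 17 heat shock genes 16 were below 0 and 0 passed the threshold, with a median of -0.28 (percentile 0.24) and DNAJB4 at -0.98. Of 29 cell cycle genes the mitotic kinases AURKA (2.13-fold) and PLK1 (2.11-fold) were lower and 0 higher. The cell cycle median was -0.19 (percentile 3.13), the mean was -0.32 (percentile 0.00), and CDK1 and CCNB2 lay at -0.79 and -0.75. Of 365 ZNF genes 3 were lower, ZNF252P, ZNF429 and ZNF596, and 0 higher, with a median of -0.11 (percentile 0.00). The 10 metallothionein and zinc genes lay inside the central 95% of random lists, with a median of -0.18 (percentile 7.35) and 0 past the threshold, with the zinc exporter SLC30A1 at -0.98.

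Replication-dependent histone genes, whose mRNAs lack poly(A) tails, lay mostly higher on the same array. All 51 were between the thresholds, 38 were above 0, and the median was 0.21 (percentile 100.0). The 177 small non-coding RNAs held 9 members higher and 2 lower, with a median of 0.26 (percentile 100.0). Unnamed probe sets also lay mostly higher on this array, and explanations from the sample rather than the treatment, given further below, stay open. Ribosomal protein genes (60) had 0 members past the threshold and a median of -0.046 (percentile 62.1), which became 0.033 after loess. Housekeeping genes (22) had a median of -0.090 (percentile 39.2) and 0 past the threshold. Of 22 monocyte identity genes S100A12 was lower and 0 higher, and the median of 0.035 (percentile 99.5) and the mean of -0.054 (percentile 63.0) differed in sign. Other cell types again had 0 members past the threshold, with medians of 0 (percentile 61.2) for 5 other blood cell markers and 0.028 (percentile 87.7) for 3 epithelial, stromal and endothelial markers. KRT18, one of the latter, was at 0.74 on one probe set and 0.12 on another.

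**Figure D2:**
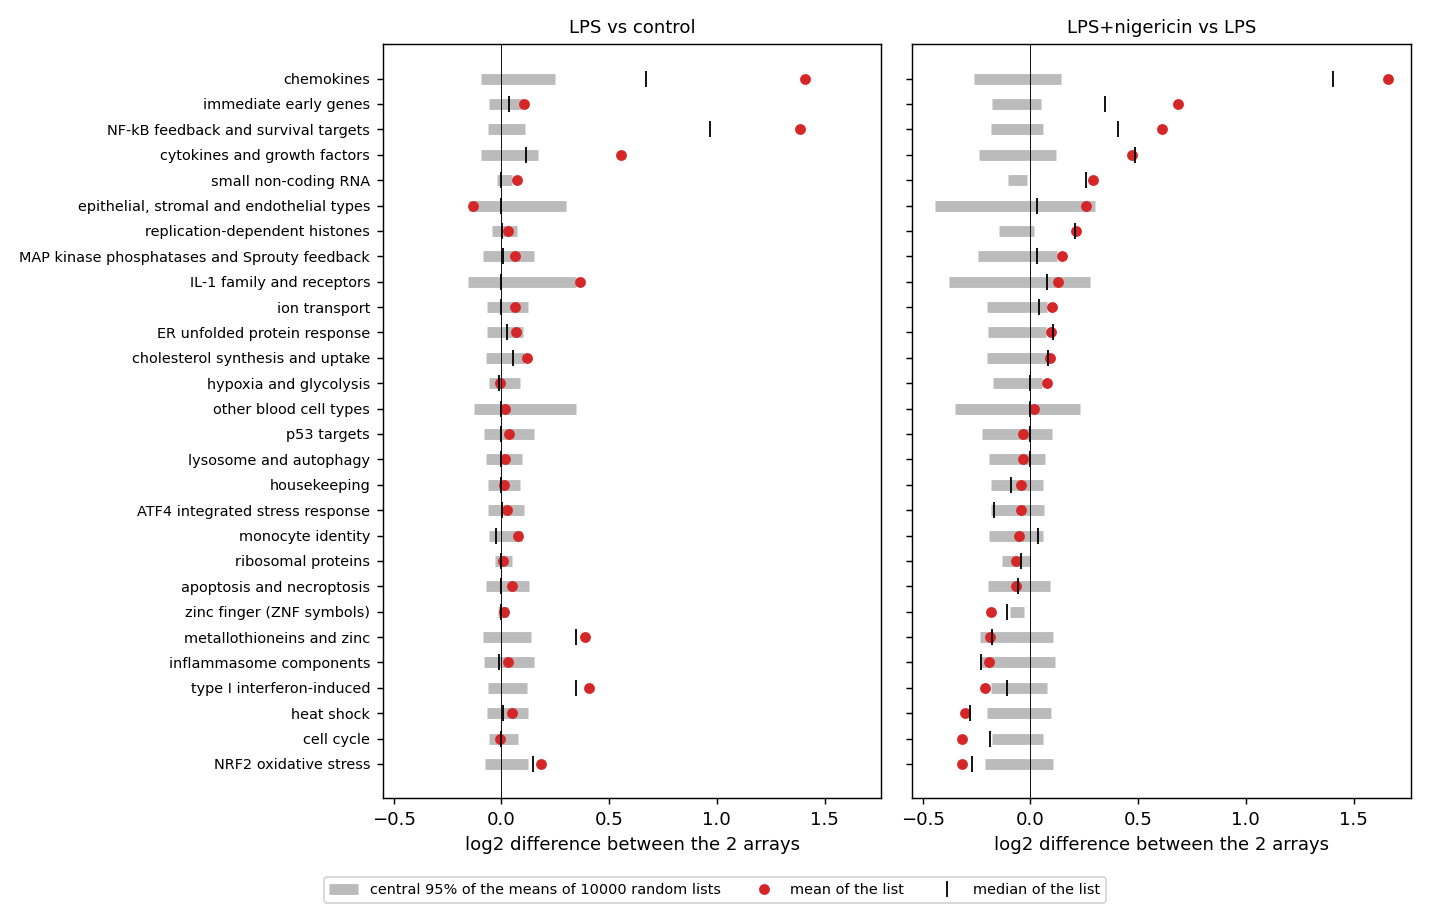
Log2 difference between 2 arrays (horizontal axes) for each gene list with measured members, for LPS against control (left) and LPS plus nigericin against LPS (right). Red points are list means, black ticks are list medians, and grey bars span the central 95% of the means of 10000 level-matched random lists. The chemokine median was 0.67 over 8 measured members on the left and 1.41 over 10 on the right. CCL4 and CXCL2 were counted on the right alone, through their values on the LPS plus nigericin array. The 2 medians therefore cover different genes.

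Both signals against neither gave more genes past the threshold than either step alone. CXCL10 was 168.3-fold higher with LPS plus nigericin than in control cells, TNFAIP6 122.4-fold, CCL4 54.2-fold, CCL3 23.8-fold and EBI3 20.5-fold. Of these, CXCL10, TNFAIP6, CCL4 and EBI3 had control values below the level filter, as IL1B did, so the exact sizes of their folds are uncertain. NFE2 was 4.97-fold lower, MTND2P28 3.65-fold, SLC40A1 3.52-fold, the chemokine receptor CCR2 3.12-fold (log2 -1.64, and -1.55 on its other probe set) and MYC 3.11-fold. IL1B was 7.41-fold higher and TNF 6.28-fold. Of 14 measured inflammasome components 1 was at least 2-fold higher, P2RX7 (2.70-fold), and 1 lower, NLRP12 (2.08-fold), a modulator of NF-kB signalling. NLRP12 was at 5.87 with LPS plus nigericin, where NFE2 and SLC40A1 also lay below the level filter, so the exact sizes of these folds are uncertain. IL18 was 1.98-fold lower, PYCARD 1.94-fold, NLRP3 1.82-fold and CASP1 1.30-fold. In all, 171 of 10987 genes were at least 2-fold higher and 76 lower, with 423 higher and 640 lower at 1.5-fold.

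Genes higher after LPS were followed after nigericin. Of 80 genes at least 2-fold higher in LPS against control, among 11011 genes that passed the level filter on any of the 3 arrays, 11 were at least 2-fold higher again with nigericin and 1 was lower. Their median nigericin difference was 0.27, and 62 lay above 0 and 17 below. This choice of genes shares the LPS array with the outcome, which pushes the outcome down. CCL4, among both the 80 and the 11, passed the level filter on the LPS plus nigericin array alone, which pushes the other way. In 100 simulations of 3 unchanged arrays, 37.4 genes on average were picked, of which 0.04 were higher and 17.5 lower, and the median was -0.72. Picking instead the 171 genes at least 2-fold higher in LPS plus nigericin against control pushes the outcome up. Of these, 54 were higher with nigericin than with LPS alone and 0 lower, with a median of 0.65, against 18.4 higher, 0.04 lower and a median of 0.78 in the simulations, which picked 39.2 genes on average. Independent lists would share 0.458 higher and 0.443 lower genes in the first selection and 0.978 and 0.947 in the second. Neither reference value holds both the real differences and the shared array, so the excess over either is not a measure of a joint effect. The simulated errors were drawn from LPS against control differences with random signs, real differences included.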

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

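In this part the comparisons within single classes of level were chosen after the result was seen. The other tests were set beforehand.

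Of 4203 unnamed probe sets numbered below the first one in the annotation table, which take part in no gene comparison, 490 were at least 2-fold higher and 76 at least 2-fold lower on the LPS plus nigericin array than on the LPS array (median 0.19), against 88 and 39 for LPS over control, with medians from 0.19 to 0.48 in the lower 6 of 8 classes of level and of -0.0878 and -0.0959 in the upper 2. Over the full range, protein-coding probe sets without ties and matched on level had a median of -0.0623 (bootstrap range -0.0751 to -0.0497). Their medians fell with level, from 0.1351 in class 1 to -0.1729 in class 7, so the pooled value does not settle a level-dependent shift. In classes 4, 5 and 6 they were -0.0694, -0.1324 and -0.1426, against 0.41, 0.48 and 0.21 for the unnamed probe sets. These opposite signs argued against a shift shared by both kinds of probe set there. In class 3 their median was 0.0088 (-0.0297 to 0.0361) against 0.37. Such a shift stays open in the lowest of the 8 classes, where their median was 0.1351 and that of the unnamed probe sets 0.19. In the class above their median was 0.0904 (0.0603 to 0.1422) against 0.33 (0.2865 to 0.389), and whether a shift contributed there is not settled. Ties were found on 4.62% of these unnamed probe sets and on 63.9% of the 1-symbol ones. In the median polish simulation a true 0.3 was estimated at 0.152 with 25 probes and 0.27 with 4. Matching on level does not correct for such shrinkage, so the sizes of these medians cannot be compared directly. More nuclear or unspliced RNA in the nigericin sample may contribute, as the mean of 145 long non-coding RNA genes was 0.038, at percentile 99.99 of level-matched random lists, although their median was 0 at percentile 50.2. Most random means lay between -0.1037 and -0.0083. The long non-coding RNA genes thus stayed near 0 where matched genes lay lower, and a rise of them is not shown. Residual genomic DNA may contribute too, since of 2595 low-level protein-coding genes 544 lay above 0, 141 below and 1910 exactly at 0, a ratio of 3.858 among those that differed, which a shift confined to low levels would also give. A true change with nigericin stays open and untested. The small non-coding RNA and histone lists also leaned higher, which does not tell these explanations apart. The unnamed probe sets also varied more than 1-symbol ones (SD 0.617 against 0.259 here, and 0.386 against 0.181 for LPS over control), which unlike shrinkage may affect. What they measure is not given in the sources used here, and 1 array per condition ties every property of a sample to its treatment.

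Exact ties between arrays were a second pattern, found on 58.4% of all probe sets and on 4.62% of the low-numbered unnamed ones. The tables argued against rounding of the deposited values, with 23 differences between 0 and 0.0005 against 16682 exact ties for LPS over control, a ratio of 0.0014. Median polish of 3 arrays is a candidate explanation, since simulated unchanged probe sets of 25 probes held a tie in 97.4% of cases, and those of 4 probes in 4.8%. Across 10 equal classes of level the tie share was 78.4% in the lowest class, 83.6% in the next and 17.2% in the highest. No biological explanation was tested.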

How the results depend on the processing

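All alternative settings in this part were planned. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. Centring each pair on its median difference changed nothing, as that median was 0 in all 3 pairs, so it says nothing about stability. With loess on level, 328 log2 differences of named genes and medians of lists and 10 counts stayed within the tolerances of 0.585 on the log2 scale and 1.5 times for counts, as 328 and 6 did with the mean of all probe sets. With no level filter 6 counts and 55 list medians stayed within them. Most list medians were themselves smaller in size than 0.585, so staying within that tolerance says little about them. The mean of all probe sets can change values for the 769 genes with several probe sets alone. A sign that turned under loess was the small ribosomal protein median for nigericin, from -0.046 to 0.033. Counts moved with the threshold by its own construction. At 1.5-fold there were 185 higher and 33 lower genes for LPS, 258 and 498 for nigericin against LPS, and 423 and 640 for both against control. At 3-fold there were 28 and 0, 19 and 4, and 79 and 6. With the level filter at the 75th percentile, which tests fewer genes, 47 genes were higher and 0 lower for LPS, 32 were lower for nigericin against LPS and 44 lower for both against control. Of the genes picked on LPS against control, 42 were higher and 14 lower with nigericin at 1.5-fold and 3 and 0 at 3-fold. Of those picked on both signals against control, 207 were higher and 2 lower at 1.5-fold and 19 higher at 3-fold. The 75th percentile filter turned the MAP kinase phosphatase and Sprouty median for LPS from 0.0078 to -0.0432 and for nigericin from 0.029 to -0.38, and the inflammasome median for LPS from -0.0125 to 0.0159. The cause was not tested. It raised the chemokine median to 2.08 for LPS and 2.06 for nigericin, the NF-kB median for LPS to 1.59 and the IL-1 family median for nigericin to 0.71, and no filter lowered the chemokine median for nigericin to 0.085. The filtered chemokine medians were the values of CCL2 and CCL20, and the IL-1 family one rested on IL1B and IL1RN alone. Without background signals, differences of genes near the bottom of the range are the least certain.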

Other observations

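Small non-coding RNAs were not to be named one by one, and the following were chosen after their values were seen. MIR223 and MIR142, microRNA loci active in myeloid cells, were lower on the LPS plus nigericin array than on the LPS array, with log2 differences of -1.69 and -1.56. These were the 2 members of the 177 measured that were at least 2-fold lower. The H/ACA small nucleolar RNAs SNORA50A and SNORA67, which guide pseudouridylation, were at 1.48 and 1.20, among 9 members at least 2-fold higher, and 133 of the 177 lay above 0 and 23 below.

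Histone members with the largest differences were H2AC15 at 0.85, H3C7 at 0.71 and H4C2 at 0.60, and H1-6 lay opposite at -0.84. Of 145 measured long non-coding RNA genes 3 were at least 2-fold higher with nigericin and 0 lower. Probe sets that list several symbols, which named no gene, held 21 higher and 1 lower with nigericin against LPS, and 8 higher and 1 lower with LPS against control.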
